A study of Arabidopsis thaliana with 27 samples.

How the data were processed

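RNA from Arabidopsis thaliana egg cells, zygotes and early embryos was sequenced in 27 libraries, 3 in each of 9 groups. In the accession Columbia (Col) the groups were egg cells (EC), zygotes 14 hours after pollination (Zy14, spherical), zygotes 24 hours after pollination (Zy24, elongated), 1-cell embryos (1C) and 32-cell embryos (32C). The other 4 groups were zygotes from crosses between Col and Landsberg erecta (Ler) at the same hours. LZy14 and LZy24 come from the cross whose label names Ler first, and CZy14 and CZy24 from the cross whose label names Col first. The labels do not state which parent was the mother. Per the labels, polyadenylated RNA was captured on beads, cDNA was made and amplified with a SMART-Seq Ultra Low Input kit, and libraries were made with a NEBNext Ultra DNA kit.

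The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped total), made by the authors, with 2 decimals and 1 table per library. The submitters' processing notes name TopHat2, RSEM and the TAIR10 build without versions or the step each served, and they record no scaling between libraries. Each table lists only genes above 0, from 0.01 FPKM upwards, so a gene absent from a library's table was taken as 0 for that library and is written here as listed at 0. Of 24607 genes listed in at least 1 library, 24511 were found by locus tag in the annotation used for gene names and product descriptions, 23459 of them protein coding, and 96 were not found. No plastid or mitochondrial locus was listed. Genomic positions are not given, because the annotation used is a later release than the build named by the submitters. The tables hold no read counts. The depth was estimated from steps in the low values of 14197 genes with 1 annotated transcript, and 1 fragment per kb came out at 0.043 to 0.0878 FPKM, so the deepest library was 2.04 times the shallowest. Estimates from 2 separate sets of these genes, a check added after the results were seen, were at most 10% apart in 25 of 27 libraries (median 2.8%), but 68.5% apart in EC replicate 2, whose depth is uncertain. No counting interval or detection floor is given, since the steps give no count for each gene. The FPKM sum per library ranged from 746880 to 940207.

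Differences were tested with limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1), with empirical Bayes moderation, a trend in the variance, robust estimation and Benjamini-Hochberg adjustment over all genes kept. The 15 Col libraries shared 1 fit, with 18481 genes, and the 18 zygote libraries shared another, with 18815 genes, each keeping genes with FPKM of at least 1 in at least 3 libraries. The values were used as deposited. A gene was called at an adjusted p under 0.05 and an absolute log2 change of at least 1, and rose or fell is written only of called genes. Adding 1 before the logarithm makes the log2 change of weakly expressed genes too small. The contrasts were each stage of the Col series against the stage before it, 24 against 14 hours within each cross, the 2 crosses against each other at each hour, the change of that difference from 14 to 24 hours, and the mean of the crosses against Col at each hour. In the fits that share an estimate of the spread, the median standard error of a contrast was 0.334 (Col series), 0.403 (zygotes), 0.57 (change of the reciprocal difference) and 0.349 (hybrids against Col). Numbers of genes with FPKM of at least 1 were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Genes were counted as switched on or off in a Col step when all 3 libraries of 1 stage had FPKM under 1 and all 3 of the other at least 5. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

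In all 21 gene lists were tested with camera from limma, at its preset correlation between genes and again with an estimated correlation, with adjustment over the lists of a comparison (20 in the Col steps, 19 in the others). The 20 lists fixed by name held 249 genes, 3 of which were listed in no library. They covered egg cell genes, zygote polarity and YODA pathway, embryo patterning regulators, embryo maturation regulators, auxin, DNA replication, mitosis, H3 histones, H4 histones, ribosome biogenesis, RNA polymerase II and general transcription, mRNA decay and poly(A) binding, DNA methylation with small RNA and Polycomb, cellulose synthesis and cytoskeleton, stress and wounding, photosynthesis, and markers of the central cell and endosperm, synergids, seed coat and ovule integument, and sperm and pollen. The last list, cytosolic ribosomal proteins, took 322 genes by their product description, which also brings in elongation factors such as LOS1 and some proteins that resemble organellar ones. Lists with fewer than 3 tested members are given as counts only. Of 213 list tests, 43 passed at the preset correlation and 2 with an estimated correlation, both in the comparison of 32C with 1C. Counts of called members are also given adjusted over the list alone.

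The genes named are, per comparison, the called genes with the largest rises and falls among those whose groups do not overlap and whose higher group averages at least 20 FPKM (6 each way, 4 for hybrids and for the change of the reciprocal difference) and up to 3 called members of each list. To these comes a fixed set (EC1.1, EC1.2, RKD4, WOX2, WOX8, WOX9, HDG11, SSP, YDA and WRKY2 in each Col step, ER and SSP between crosses). Near-identical copies and genes without a product name may be left out. A gene that the rule names is not reported here. For the change of the reciprocal difference, the requirement of no overlap was read as no overlap between the crosses at 14 or at 24 hours, a reading settled after the data were seen. The groups, contrasts, tests, thresholds, lists, this rule and the alternatives were chosen before the data were examined, except where stated. The alternatives were a pseudocount of 0.1, no filter and a filter of FPKM at least 5, scaling to equal sums per library, median of ratios scaling, quantile normalization, the replicate number as a block, only the compared groups in the fit, each library left out in turn, and for counts of genes other FPKM thresholds. Fits without EC replicate 3 and Zy14 replicate 1, the libraries with the most synergid transcripts, were added after the data were seen. So were fits without LZy24 replicates 1 and 3.

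The method was tested on simulated values drawn from the mean and spread of each real gene, with a known change added to 100 genes of each size among those above 10 FPKM. A log2 change of 1.5 was recovered in 77% (Zy14 against EC), 71% (Zy24 against Zy14) and 61% (LZy24 against CZy24) of these genes. A change of 3 was recovered in 100%, 95% and 93%, and 6, 6 and 5 unchanged genes were called. The simulated spread was independent between genes and the same in all groups, and far fewer genes changed than were called in the real comparisons. These rates therefore need not hold for the real data. The replicate numbers do not pair the libraries: the correlation of deviations from the group means exceeded 0.1 in 3 of 108 pairs of same-numbered libraries (range -0.069 to 0.199), so no block was used. Nothing in the labels says that the replicates came from separate plants or collections, so the p-values measure only the spread between these samples. LZy14 replicate 3 lay close to a weighted mean of LZy14 replicates 1 and 2 (weight 56% on replicate 1). Its median distance from that mean was 0.0472 log2 over 12372 genes, 87.0% of which lay between the other libraries, against a next lowest distance of 0.118 for 32C replicate 2. CZy14 replicate 3 stood apart, with a median distance of 0.505 log2 from the best weighted mean of CZy14 replicates 1 and 2, the largest of all libraries, while these 2 lay 0.128 from each other. The lists of called genes of comparisons that share libraries were not compared with each other. Allele-specific values are not analysed here, since the tables hold 1 value per gene.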

Results

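The series follows gene expression from the egg cell through the zygote to the 32-cell embryo of Arabidopsis thaliana, with zygotes of reciprocal crosses to look at the contribution of each parent. Each of 27 libraries gives FPKM values of nuclear genes, with 3 libraries in each of 9 groups, and lists between 14902 and 20062 genes above 0. Levels below are mean FPKM ± SD with n = 3 and log2 changes are given ± SE, unless single libraries are listed in the order of their replicate numbers. In EC the 10 highest genes took 14.6 ± 2.48% of the summed FPKM, against group means of 2.96% to 4.32% in the other 8 groups, and EC1.1 was the highest gene of each EC library at 21833 to 32564 FPKM.

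The number of genes with FPKM of at least 1 was 14288 ± 445 in EC, 16584 ± 446 in Zy14, 14247 ± 422 in Zy24, 15251 ± 183 in 1C and 15830 ± 128 in 32C. Each of these 4 steps, of 2296, -2337, 1004 and 579 genes, separated all libraries of the groups, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.12 over 6 comparisons). The steps were 1582, -825, 279 and 579 genes at FPKM of at least 5 and 2833, -3242, 1416 and 1518 at 0.1. Over 27 libraries the number had a Spearman correlation of 0.145 with the estimated depth. The ratio of mean depth was 1.12 (Zy14 to EC, where EC replicate 2 is uncertain), 1.13 (Zy24 to Zy14), 1.01 (1C to Zy24), 0.88 (32C to 1C), 0.97 (LZy14 to CZy14) and 0.84 (LZy24 to CZy24). LZy24 (15014 ± 215) held 1043 genes more than CZy24 (13971 ± 300) with the same exact p of 0.1, but 64 fewer (-64) at FPKM of at least 5, while LZy14 (15665 ± 442) and CZy14 (16305 ± 149) overlapped (exact p = 0.2).

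Between the egg cell and the zygote at 14 hours, all 10 egg cell genes fell, and regulators of the zygote and embryo that were listed at 0 in the egg cell libraries were present. ECS1, an aspartyl protease of the egg cell, fell from 20896 ± 759 to 2772 ± 812 (log2 change -2.95 ± 0.18, adjusted p = 3.23e-08). EC1.1, a secreted protein that activates sperm, fell from 25958 ± 5780 to 5474 ± 1773 (-2.28 ± 0.32, adjusted p = 8.55e-05). The set test gave an adjusted p of 9.5e-11 over 20 lists for the egg cell genes, or adjusted p = 0.161 with an estimated correlation. Quantile normalization ended these calls, with log2 changes of -0.23 for ECS1, -0.63 for ECS2, 0.00 for EC1.1 and -0.78 for EC1.2. It turned EC1.3 to 0.28 from -2.39. EC1.1 was the highest gene of every EC and Zy14 library. Quantile normalization gives the highest gene of each library the same value, so the 0.00 of EC1.1 was fixed in advance. The pectin lyase-like gene AT3G59850 (48.2 ± 9.28 to 1.02 ± 0.95, -4.71 ± 0.33, adjusted p = 9.8e-08) and the glycosyl hydrolase MAN7 (70.6 ± 29.6 to 2.44 ± 0.45, -4.28 ± 0.79, adjusted p = 0.000769) also fell.

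Of 19 genes of zygote polarity and the YODA pathway, 7 rose and 1 fell at 14 hours (adjusted p = 0.111 for the set). RKD4, an RWP-RK transcription factor needed for early embryo development, rose from 109 ± 11.5 to 464 ± 121 (2.05 ± 0.24, adjusted p = 1.36e-05). WOX9 (115, 111 and 18.4 in Zy14, adjusted p = 4.45e-07) and the kinase-like YODA activator SSP (60.15, 55.7 and 15.5, adjusted p = 3.21e-07) were listed at 0 in all EC libraries. So were the kinase MKK5 (17.9, 18.8 and 16.5, adjusted p = 1.21e-07) and the apical homeobox gene WOX2 (3.02, 3.63 and 5.97, adjusted p = 1.55e-05). WOX8 went from 175 ± 46.1 to 380.4 ± 90.2 (1.12 ± 0.28, adjusted p = 0.0061), a call lost without Zy14 replicate 2 (0.96), without EC replicate 2 (0.945) and after median of ratios scaling (0.91). HDG11 (0.24, adjusted p = 0.585), YDA (0.95, adjusted p = 0.0123) and WRKY2 (0.38, adjusted p = 0.275) were not called. Of 18 embryo patterning regulators 7 rose and 1 fell (adjusted p = 0.0696 for the set). BBM (198, 158 and 66.1) and PLT2 (115, 75.6 and 48.7), AP2-type transcription factors, were listed at 0 in EC, and the epidermal regulator ATML1 rose from 3.01 ± 1.06 to 28.9 ± 7.33 (2.90 ± 0.28, adjusted p = 2.52e-06). The lipoxygenase LOX5 (374, 252 and 192) and the F-box gene DAF1 (2015, 3360.4 and 46.5, lowest in Zy14 replicate 3) were also listed at 0 in EC.

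DNA replication genes rose as a group at 14 hours, 10 of 14 higher and 1 lower, or 10 and 2 adjusted over the list alone (set adjusted p = 0.0293, adjusted p = 0.452 with an estimated correlation). MCM3, a subunit of the replicative helicase, rose from 0.50 ± 0.65 to 41.0 ± 19.6 (4.76 ± 0.40, adjusted p = 7.15e-07), and MCM5 from 3.33 ± 0.88 to 22.7 ± 11.8 (2.32 ± 0.35, adjusted p = 0.000142). Among histones, 5 of 8 H4 genes and 5 of 9 H3 genes rose, with set adjusted p of 0.0978 and 0.127, among them H4h (3.89 ± 1.9 to 51.5 ± 7.16) and HTR3 (6.01 ± 1.3 to 48.3 ± 23.9). Of 10 stress and wounding genes 7 rose (set adjusted p = 0.00632, adjusted p = 0.452 with an estimated correlation), including the zinc finger gene ZAT12 at 348, 259 and 259.8 in Zy14 and 11.5, 0 and 46.1 in EC. CAF1B, a subunit of the deadenylase that shortens poly(A) tails, rose from 25.8 ± 18.1 to 268 ± 63.9 (3.52 ± 0.47, adjusted p = 5.52e-05). It is 1 of 2 genes that rose among 14 of mRNA decay and poly(A) binding (set adjusted p = 0.488). Cytosolic ribosomal protein genes lay lower as a set, with a median log2 change of -0.30 over 313 genes of which 8 rose and 7 fell (set adjusted p = 5.28e-09, adjusted p = 0.489 with an estimated correlation).

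Of 6 synergid markers 2 fell and none rose (set adjusted p = 0.0293, adjusted p = 0.479 with an estimated correlation). DD31 and LURE1.2, chosen after their values were seen, stood out in single libraries. DD31 was at 12.6, 0 and 57.9 in EC and 214, 0 and 0.45 in Zy14. LURE1.2 was at 12.2, 2.04 and 65.8 in EC and 300.3, 0 and 0 in Zy14. In the list of DNA methylation, small RNA and Polycomb 1 of 27 genes rose and 3 fell (set adjusted p = 0.114), AGO4 falling from 77.2 ± 8.87 to 33.5 ± 4.16. The list median of 0.04 became -0.16 after median of ratios scaling and -0.42 after quantile normalization. LEC2 rose from 2.22 ± 1.7 to 28.1 ± 5.77, 1 of 2 that rose among 6 embryo maturation regulators (set adjusted p = 0.5). ACT11 fell from 332 ± 25.4 to 101 ± 43.2 in the cellulose and cytoskeleton list (1 rose and 1 fell of 8, set adjusted p = 0.875). HAP2 fell from 14.8 ± 1.75 to 3.63 ± 2.05 among sperm and pollen markers (1 of 4 fell, set adjusted p = 0.233). In the remaining lists 2 of 13 auxin genes rose and 2 fell (set adjusted p = 0.552), 2 of 5 central cell and endosperm markers rose, or 3 adjusted over the list alone (0.233), and 1 of 16 mitosis genes rose (0.72). No gene was called among 16 of ribosome biogenesis (0.982), 7 of RNA polymerase II (0.127), 6 photosynthetic genes (0.608) and 2 seed coat markers, which are too few for the set test. Counts adjusted over the list alone were the same for all lists but DNA replication and central cell. The set test pointed down, against a positive median, in the cellulose (0.23), mitosis (0.48) and DNA methylation (0.04, mean -0.07) lists and, against a positive mean, in the auxin (0.16) and photosynthetic (0.30, median -0.12) lists.

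In total 3611 genes were higher and 1139 lower in Zy14 than in EC, 76.0% of the calls being higher, and the groups did not overlap in 40.2% of tested genes against 10% by chance. The higher share was 80.9% after scaling to equal sums, 66.9% after median of ratios scaling and 49.0% after quantile normalization (2403 higher, 2497 lower). The median log2 change of all genes moved from 0.228 to 0.336, 0.067 and -0.092, so each change above is relative to that centre. Without EC replicate 3 and Zy14 replicate 1, the libraries with the most synergid transcripts, 3121 genes were higher and 978 lower. Genes switched on numbered 383 (587 without Zy14 replicate 3). Genes switched off numbered 11 (20 without Zy14 replicate 1, 26 without Zy14 replicate 3, 28 without EC replicate 2 and 27 without EC replicate 3), while another split of the same libraries gave 26.

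From 14 to 24 hours egg cell genes fell and histone and division genes rose. EC1.1, EC1.2, EC1.3, ECS1 and ECS2, at means of 2043 to 5474 in Zy14, were listed at 0 in all Zy24 libraries (adjusted p of 1.77e-12 for EC1.1 and 1.1e-14 for ECS1). The same libraries list BRX1-1 and other genes present at the other stages near 0, so a 0 there does not prove absence, and EC1.1 was at 5.57, 1.24 and 3.73 in 1C. Of the list 9 of 10 egg cell genes fell (set adjusted p = 9.7e-10, adjusted p = 0.106 with an estimated correlation). WOX2 rose from 4.21 ± 1.56 to 229 ± 83.4 (5.43 ± 0.28, adjusted p = 2.87e-09) and LEC2, a regulator of embryo identity, from 28.1 ± 5.77 to 219 ± 25.6 (2.93 ± 0.29, adjusted p = 2.34e-06). Among H3 histones 8 of 9 rose (set adjusted p = 0.000226, adjusted p = 0.106 with an estimated correlation) and among H4 histones 6 of 8 (0.000292, adjusted p = 0.285 with an estimated correlation). They include the centromeric histone HTR12 (5.35 ± 3.57 to 68.5 ± 11.3, 3.61 ± 0.35, adjusted p = 1.7e-06) and H4g (126 ± 22.8 to 877 ± 283). Of 16 mitosis genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (set adjusted p = 0.000884, adjusted p = 0.536 with an estimated correlation). CDKB1;1 rose from 13.2 ± 2.98 to 126 ± 50.5 and the kinase AUR1 from 2.08 ± 0.78 to 65.9 ± 33.2. Zy24 replicate 1 lay low in this list, with CYCB1;1 at 0 against 37.5 and 31.9 in replicates 2 and 3.

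Replication factors parted between these hours, with PCNA1 rising (39.6 ± 7.54 to 103 ± 40.3, 1.28 ± 0.32) and MCM3 (41.0 ± 19.6 to 8.71 ± 1.55, -1.99 ± 0.40) and the licensing factor CDT1A (56.3, 77.7 and 12.8 to 0.28, 7.64 and 6.49) falling. In their list 1 of 14 rose and 4 fell, or 3 adjusted over the list alone (set adjusted p = 0.773). AGO5, an argonaute, fell from 290.5 ± 53.1 to 18.5 ± 2.89 (-3.90 ± 0.18, adjusted p = 1.31e-09) and AGO9 from 867 ± 93.1 to 393 ± 29.1 (-1.14 ± 0.14). CAF1B returned from 268 ± 63.9 to 12.4 ± 7.51 (-4.51 ± 0.47, adjusted p = 3.94e-06), and HSP90.1 fell from 333 ± 191 to 33.8 ± 15.3 among 5 of 10 stress genes that fell (set adjusted p = 0.111). The receptor kinase ER (25.5 ± 4.26 to 8.08 ± 0.80) and the kinase MPK3 (135 ± 57.4 to 21.0 ± 3.39) fell. RKD4 went from 464 ± 121 to 242 ± 15.7 without being called (-0.90 ± 0.24, adjusted p = 0.00605). WOX9 went from 81.8 ± 54.9 to 228 ± 50.6 (1.83 ± 0.48, adjusted p = 0.00599), a call lost without Zy14 replicate 3 (0.98) and with only the compared groups in the fit (1.83). WOX8 (0.15), SSP (-0.37), HDG11 (-0.35), YDA (-0.38) and WRKY2 (0.33) were not called, with adjusted p from 0.254 to 0.683. Ribosomal protein genes rose as a set, 61 higher and 15 lower of 313, or 61 and 17 adjusted over the list alone (set adjusted p = 1.28e-07, adjusted p = 0.626 with an estimated correlation). In ribosome biogenesis 5 of 16 fell (set adjusted p = 0.0111, adjusted p = 0.194 with an estimated correlation). Among them were APUM24 (75.4 ± 10.9 to 21.6 ± 4.86) and BRX1-1, a ribosomal RNA processing gene. BRX1-1 is 1 of 10 genes near 0 in all Zy24 and CZy24 libraries and LZy24 replicate 2 and present in LZy24 replicates 1 and 3. The set test was not repeated without BRX1-1. In the hybrid steps the list did not pass, with 2 of 16 falling in the LZy zygotes (set adjusted p = 0.832) and 3 in the CZy zygotes (0.274). Of 5 central cell and endosperm markers 3 fell, or 4 adjusted over the list alone (set adjusted p = 0.044, adjusted p = 0.194 with an estimated correlation). Of other markers 2 of 4 of sperm and pollen and 1 of 6 of synergids fell, without the sets passing (0.183 and 0.611).

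At this step 2987 genes were higher and 3984 lower, and groups did not overlap in 50.6% of tested genes against 10% by chance. The higher share of 42.8% was 37.5% after scaling to equal sums and 52.0% after quantile normalization (3489 and 3223). The median log2 change of all genes was -0.068, or -0.179 after scaling to equal sums and 0.051 after quantile normalization. Without Zy14 replicate 1 and EC replicate 3 the calls numbered 6273. Genes switched off numbered 516, headed by EC1.1, and genes switched on 60 (114 without Zy24 replicate 1, 102 without Zy24 replicate 2 and 100 without Zy14 replicate 3), such as the early nodulin-like ENODL13, chosen after its values were seen.

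**Figure D1:**
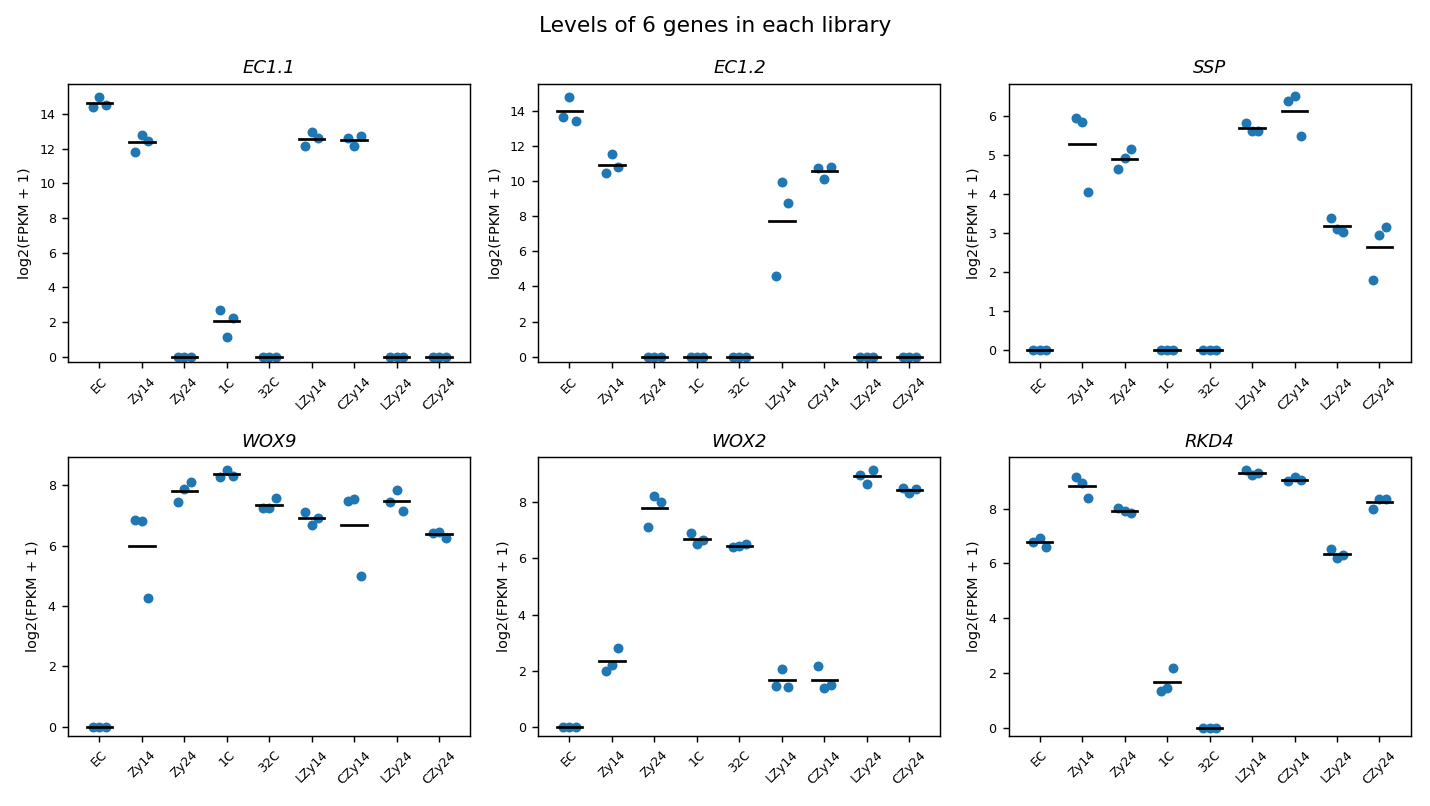
Levels of EC1.1, EC1.2, SSP, WOX9, WOX2 and RKD4 as log2(FPKM + 1) on the vertical axis in the 9 groups on the horizontal axis, where each point is 1 library and each line the mean of 3. EC1.1 and EC1.2 are highest in EC and at 0 at 24 hours, WOX2 is low at 14 hours and high at 24 hours, and RKD4 is low in 1C and at 0 in 32C.

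The step from the elongated zygote to the 1-cell embryo took RKD4 from 242 ± 15.7 to 2.27 ± 1.12 (-6.27 ± 0.24, adjusted p = 3.72e-10). SSP, at 23.9, 29.0 and 34.3 in Zy24, was listed at 0 in all 1C libraries (adjusted p = 6.59e-07). WOX8 fell from 415 ± 25.8 to 135 ± 61.0 (-1.71 ± 0.28, adjusted p = 0.000213) and WRKY2, its upstream regulator, from 58.0 ± 7.78 to 22.1 ± 4.54 (-1.36 ± 0.26). WOX2 went from 229 ± 83.4 to 104 ± 14.99 (-1.07 ± 0.28), a call lost without 1C replicate 2 (-0.98), Zy24 replicate 2 (-0.85) or Zy24 replicate 3 (-0.96) and after median of ratios scaling (-0.996) or quantile normalization (-0.98). WOX9 (0.55), HDG11 (0.485) and YDA (-0.43) were not called, and EC1.2 was listed at 0 in both stages. The signalling kinase BSK1 rose from 2.15 ± 0.25 to 31.5 ± 4.57 (3.36 ± 0.24, adjusted p = 1.33e-07). In the whole polarity list 3 of 19 rose and 5 fell (set adjusted p = 0.637), with a median of -0.05 that became 0.03 after median of ratios scaling and 0.06 after quantile normalization.

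Auxin genes rose in the 1-cell embryo, 7 of 13 higher and 1 lower (set adjusted p = 0.0205, adjusted p = 0.461 with an estimated correlation). The receptor AFB2 (22.2, 21.3 and 23.8) and the auxin response factor MP (25.8, 20.03 and 16.1) were listed at 0 in Zy24. Of 16 mitosis genes 8 rose, or 11 adjusted over the list alone (set adjusted p = 0.0166, adjusted p = 0.684 with an estimated correlation). They include AUR2 (14.1 ± 5.03 to 105 ± 51.8, 2.75 ± 0.40, adjusted p = 8.9e-05) and CYCB1;1 (0, 37.5 and 31.9 to 119.6, 385 and 204, 4.29 ± 0.99, or 2.57 without Zy24 replicate 1). MCM3 (8.71 ± 1.55 to 47.9 ± 17.3, 2.28 ± 0.40) and MCM5 (10.5 ± 1.37 to 44.1 ± 8.00) rose and E2FB fell (39.4 ± 4.70 to 12.2 ± 2.47, -1.62 ± 0.23). Of 14 DNA replication genes 6 rose and 1 fell (set adjusted p = 0.0644). Among markers of other cell types 3 of 4 of sperm and pollen rose and 1 fell (set adjusted p = 0.433), 1 of 2 of the seed coat rose and 1 of 5 of the central cell and endosperm fell, or 1 rose and 1 fell adjusted over the list alone (0.701). None of 6 synergid markers was called. H4 histones were lower as a set, with 1 of 8 falling (set adjusted p = 0.0443, adjusted p = 0.684 with an estimated correlation). In the list of DNA methylation, small RNA and Polycomb 7 of 27 genes rose and 2 fell (set adjusted p = 0.433). Among them AGO5 rose from 18.5 ± 2.89 to 191 ± 29.8 (3.31 ± 0.18, adjusted p = 1.82e-08) and AGO4 from 29.0 ± 4.17 to 167 ± 9.77 (2.49 ± 0.15). AGO9 fell from 393 ± 29.1 to 93.7 ± 5.21 (-2.06 ± 0.14). RKD3 rose from 104 ± 15.7 to 419 ± 19.6 (2.01 ± 0.24), PAB4, a poly(A) binding protein, from 103 ± 16.6 to 290.4 ± 18.2, and the decapping enzyme DCP2 fell from 84.6 ± 9.15 to 22.7 ± 4.57.

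Ribosome biogenesis genes rose, 7 of 16 higher and none lower (set adjusted p = 0.000128, adjusted p = 0.0884 with an estimated correlation). The nucleolar methyltransferases rose, FIB1 from 368 ± 28.1 to 795 ± 40.9 (1.11 ± 0.14) and FIB2 from 209.9 ± 12.6 to 512 ± 27.2 (1.28 ± 0.14). The 7 include BRX1-1, which like AT1G52930, MEE49 and IMP4, genes with the same Brix domain, is 1 of the 10 genes near 0 in 7 of the 24-hour libraries. Here too the set test was not repeated without BRX1-1. Levels in 1C were 276 ± 25.6 (AT1G52930), 143 ± 9.91 (MEE49) and 133 ± 3.96 (IMP4). In total 3073 genes were higher and 2761 lower, without overlap of the groups in 52.1% of tested genes against 10% by chance. After quantile normalization 2755 were higher and 2805 lower. Genes switched on numbered 343 and genes switched off 136 (215 without Zy24 replicate 2).

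The 32-cell embryo differed from the 1-cell embryo by a rise of patterning and auxin genes, the lists whose set tests also passed with an estimated correlation. Of 18 embryo patterning regulators 11 rose, or 13 adjusted over the list alone (set adjusted p = 3.33e-06, adjusted p = 0.031 with an estimated correlation). The vascular regulator TMO5 (27.9, 46.2 and 41.1) and the ground tissue regulator SHR (18.9, 20.4 and 19.9) were listed at 0 in 1C. WOX5, a gene of the root stem cell niche, was at 16.7 ± 4.37 against 0, 0.34 and 0.53. Of 13 auxin genes 9 rose (set adjusted p = 3.63e-07, adjusted p = 0.0298 with an estimated correlation). The auxin synthesis gene TAA1 was at 28.1 ± 1.86 against 0, 0.07 and 0.40. PDF1, an epidermal marker, was listed at 0 in 1C and reached 2829.6, 3363 and 3088 in 32C (adjusted p = 5e-13), and the lipid transfer protein LTPG1 reached 541 ± 111 against 0, 0.32 and 0.14.

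Embryo maturation regulators FUS3 (4.80 ± 2.81 to 113 ± 24.5, 4.39 ± 0.39, adjusted p = 6.91e-07) and L1L (5.74 ± 0.77 to 205 ± 36.2, 4.92 ± 0.50) rose and ABI3 (10.9, 17.0 and 18.3) was listed at 0 in 1C. In their list 3 of 6 rose and 1 fell (set adjusted p = 0.0508). Of 16 mitosis genes 1 rose and 4 fell, or 1 and 6 adjusted over the list alone (set adjusted p = 0.0489, adjusted p = 0.63 with an estimated correlation). CDKB2;2 fell from 92.6 ± 32.2 to 31.3 ± 4.38 (-1.49 ± 0.26). RKD3 fell from 419 ± 19.6 to 69.0 ± 14.8 (-2.61 ± 0.24, adjusted p = 1.22e-06) and HDG12 from 173 ± 27.5 to 69.3 ± 5.12 (-1.30 ± 0.18). ER rose from 5.19 ± 1.95 to 15.9 ± 2.40 (1.496 ± 0.26). RKD4, at 1.54, 1.72 and 3.56 in 1C, and SSP were listed at 0 in 32C. WRKY2 went from 22.1 ± 4.54 to 9.72 ± 1.95 (-1.10 ± 0.26), a call lost without 1C replicate 1 and after median of ratios scaling (both -0.98). WOX2 (-0.25), WOX8 (0.00), WOX9 (-1.002, adjusted p = 0.139), HDG11 (-0.24) and YDA (-0.87, adjusted p = 0.0229) were not called. Among ribosomal protein genes 4 rose and 16 fell of 313 (set adjusted p = 0.648), with a median of 0.03 that became -0.04 after scaling to equal sums and -0.05 after quantile normalization. The S19 family gene AT5G09500 (192 ± 5.92 to 1.06 ± 0.44) and the acidic ribosomal protein gene AT5G40040 (408 ± 47.5 to 5.44 ± 1.87) fell. CESA1, a cellulose synthase of growing cells, fell from 41.4 ± 0.82 to 17.4 ± 2.54 (-1.21 ± 0.18), and FAS1, a histone chaperone, rose from 3.37 ± 0.54 to 16.0 ± 2.71 (1.95, SE 0.295). In total 2312 genes were higher and 1575 lower, without overlap in 56.1% of tested genes against 10% by chance. Of 4 sperm and pollen markers 2 fell (set adjusted p = 0.0809), of 2 seed coat markers 1 rose and 1 fell, and no synergid or central cell marker was called. In all 354 genes were switched on and 74 switched off.

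Hybrid zygotes repeat the 14 to 24 hour step in separate libraries. In LZy24 against LZy14, EC1.1 (4549, 8015 and 6162 in LZy14) was listed at 0 at 24 hours (adjusted p = 1.17e-16). WOX2 rose from 2.25 ± 0.87 to 484 ± 80.2 (7.24 ± 0.31, adjusted p = 1.22e-11) and the bHLH gene ICE1 was at 561 ± 61.2 against 0, 0 and 0.03. Of 16 mitosis genes 14 rose (set adjusted p = 1.53e-08, adjusted p = 0.245 with an estimated correlation), such as CDKB1;2 from 4.41 ± 0.70 to 105 ± 10.5 (4.30 ± 0.24). RKD4 fell from 637 ± 37.6 to 80.0 ± 9.73 (-2.98 ± 0.17, adjusted p = 4e-10). MPK3 fell from 195 ± 24.4 to 4.16 ± 0.60 (-5.25 ± 0.26) and the gamete expressed gene GEX1 from 293 ± 110 to 0.22 ± 0.30. Ribosomal protein genes rose, 139 of 313 higher and 7 lower, or 8 adjusted over the list alone (set adjusted p = 1.49e-21, adjusted p = 0.245 with an estimated correlation). RPL24A rose from 308 ± 32.2 to 956 ± 52.0. The H3 list (6 rose and 1 fell of 9, 0.00265, adjusted p = 0.245 with an estimated correlation) and the H4 list (5 of 8 rose, 0.0123, adjusted p = 0.445 with an estimated correlation) passed as well. Both synergid markers tested fell, as did 3 of 7 of sperm and pollen (0.232), where 1 rose adjusted over the list alone, while of 6 central cell markers 1 rose and 1 fell (0.832). The stress list (8 of 9 fell, 0.000471, adjusted p = 0.27 with an estimated correlation) and the egg cell list (1 rose and 9 fell, 4.97e-09, adjusted p = 0.189 with an estimated correlation) also passed.

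In CZy24 against CZy14, WOX2 rose from 2.31 ± 1.02 to 345 ± 19.7 (6.75 ± 0.31, adjusted p = 5.51e-11). LEC1 rose from 190.5 ± 44.1 to 811 ± 68.9 (2.11 ± 0.24) and the variant histone HTA11 was at 212 ± 19.9 against 1.57, 1.43 and 0. EC1.1 and EC1.2 were again listed at 0 at 24 hours. DNA replication genes rose, 8 of 14 higher (set adjusted p = 0.00375, adjusted p = 0.27 with an estimated correlation). The other steps did not share this rise: 0 rose and 3 fell in the LZy zygotes (set adjusted p = 0.336), and 1 rose and 4 fell in Col. PCNA1 rose from 9.61 ± 7.63 to 145 ± 11.4 (4.01 ± 0.52, adjusted p = 6.63e-06) and MCM5 from 2.84 ± 0.90 to 35.0 ± 2.82 (3.25 ± 0.41). Of 16 mitosis genes 10 rose and 1 fell (0.0109, adjusted p = 0.483 with an estimated correlation). Of 9 H3 genes 8 rose (0.000496, adjusted p = 0.205 with an estimated correlation) and of 8 H4 genes 5 (0.0011, adjusted p = 0.316 with an estimated correlation). Of 313 ribosomal protein genes 118 rose and 11 fell, or 119 and 12 adjusted over the list alone (2.73e-15, adjusted p = 0.316 with an estimated correlation). ER fell from 31.1 ± 11.8 to 0.18 ± 0.05 (-4.69 ± 0.36, adjusted p = 2.05e-08). AGO5 fell from 256 ± 8.27 to 11.1 ± 3.45 (-4.45 ± 0.23) and NRPB2, a subunit of RNA polymerase II, from 39.1 ± 2.92 to 16.5 ± 5.24 (-1.24 ± 0.25). The egg cell list fell here too (1 rose and 9 fell of 10, 1.34e-08, adjusted p = 0.205 with an estimated correlation). Of 7 sperm and pollen markers 1 rose and 2 fell (0.458), 1 of 6 central cell markers fell (0.308) and no synergid marker was called.

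Calls numbered 3239 higher and 3558 lower in the LZy zygotes and 3593 higher and 4644 lower in the CZy zygotes. In the LZy zygotes the higher share of 47.7% was 37.3% after scaling to equal sums (2584 and 4346) and 50.3% after quantile normalization (3332 and 3289). In the CZy zygotes 43.6% was 35.2% (2922 and 5385) and 50.6% (3936 and 3835), and 3344 genes were higher and 4501 lower without CZy14 replicate 3. Without LZy14 replicate 3, the library near a mixture of the other LZy14 libraries, 2908 genes were higher and 2834 lower. With LZy24 replicate 2 alone for the later hour 4119 genes were called. The median log2 change of all genes was -0.033 (LZy) and -0.115 (CZy), or -0.228 and -0.315 after scaling to equal sums. Of 2970 genes higher at Zy24 than at Zy14 and tested in both fits, 1494 (50.3%) were also higher in the LZy step, where independent lists would share 533, and 1724 (58.0%) in the CZy step, where they would share 583. Of 3952 lower genes, 1717 (43.4%, against 735) and 2193 (55.5%, against 950) were also lower. In all 3 steps 1136 genes were higher, against 105 for independent lists, and 1259 lower, against 177, while 64 and 174 genes went the opposite way in the LZy step and 136 and 158 in the CZy step.

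**Figure D2:**
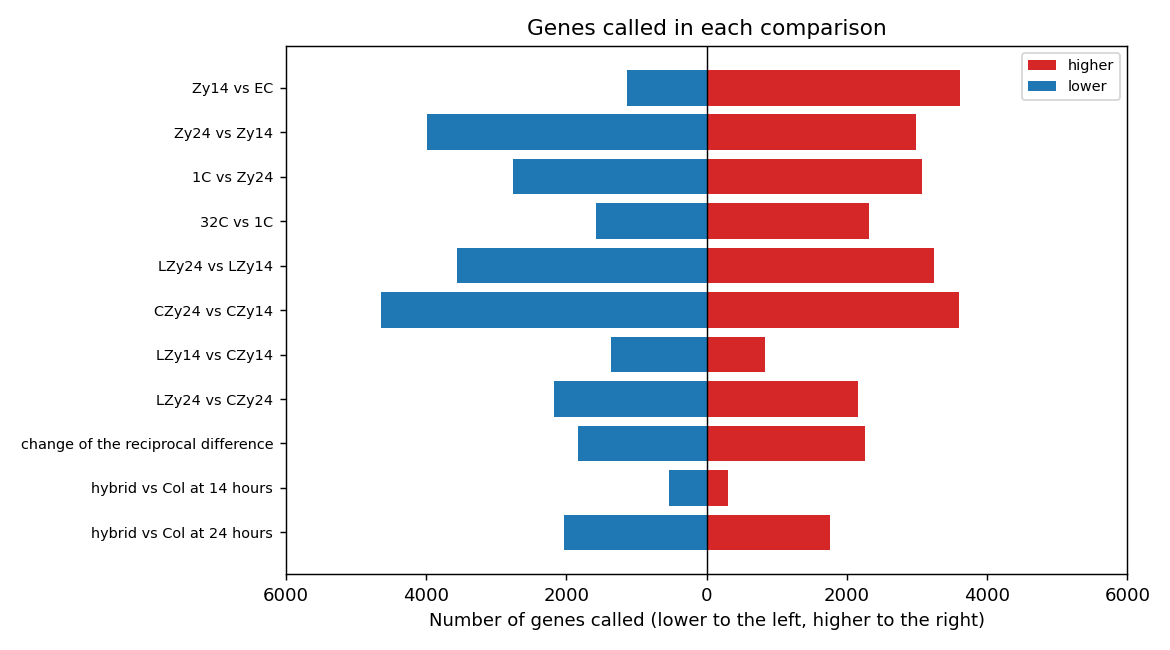
Numbers of genes called in each of 11 comparisons, with genes higher in the first-named group to the right and lower to the left of 0. The CZy step from 14 to 24 hours has the most calls and hybrids against Col at 14 hours the fewest.

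At 14 hours CYCD7;1, a cyclin D, was at 147, 298 and 214 in LZy14 and 0.33, 0 and 0 in CZy14 (adjusted p = 0.000642). Its levels in Zy14 of the Col series, looked up after its values were seen, were 119, 262 and 0.53. Of 14 DNA replication genes 5 were higher and 2 lower in LZy14, or 7 and 2 adjusted over the list alone (set adjusted p = 0.0267, adjusted p = 0.642 with an estimated correlation). MCM5 was at 24.7 ± 12.5 against 2.84 ± 0.90 (2.65 ± 0.41, adjusted p = 0.000449) and MCM3 at 27.7 ± 12.3 against 3.63 ± 2.69 (2.75 ± 0.49). ORC1A, of the origin recognition complex, was listed at 0 in LZy14 and at 4.93, 4.35 and 15.8 in CZy14. CDC20.2 (100.5 ± 4.81 against 28.5 ± 3.92, 1.79 ± 0.34) and CDKB2;1 (33.2 ± 2.61 against 14.7 ± 2.39, 1.13 ± 0.21) were higher among 16 mitosis genes (2 higher, set adjusted p = 0.875). DRN, an AP2-type regulator of the embryo, was lower (4.33 ± 2.32 against 25.1 ± 5.36, -2.38 ± 0.36, adjusted p = 0.000315). The heat shock factor AT-HSFA7B (51.2, 46.9 and 69.9 in CZy14) and GSTU8 were listed at 0 in LZy14. ER (0.17, adjusted p = 0.814) and SSP (-0.44, adjusted p = 0.553) were not called.

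Photosynthetic genes were higher in LZy14 as a set, 2 of 7 called (set adjusted p = 0.0267, adjusted p = 0.296 with an estimated correlation), LHCB1.3 being at 8.25 ± 0.64 against 0.22, 0 and 0. The ribosomal protein set was higher with 5 of 313 higher and 6 lower (0.0267, adjusted p = 0.981 with an estimated correlation). Both synergid markers tested were higher in LZy14, LRE (3.02, 8.33 and 5.34 against 0.86, 0 and 1.16, adjusted p = 0.00224) and NTA (9.02, 6.35 and 8.07 against 2.29, 2.98 and 0, adjusted p = 0.0203). NTA lost its call at a pseudocount of 0.1, with only the compared groups in the fit and without any of 3 single libraries, and DD31 and LURE1.2 were listed at 0 in all 6 libraries. Of 7 sperm and pollen markers 2 were higher, or 3 adjusted over the list alone (set adjusted p = 0.161). None of 6 central cell and endosperm markers (median -0.62, 0.667) or 2 seed coat markers was called. In all 829 genes were higher and 1358 lower in LZy14, or 439 and 828 without LZy14 replicate 3, the library near a mixture of the others, and 1414 genes were called without CZy14 replicate 2. Without CZy14 replicate 3, which stands apart from the other 2, the calls were 797 and 1387. The higher share of 37.9% was 49.2% after quantile normalization (1100 higher, 1134 lower).

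At 24 hours mitotic genes were higher and replication genes lower in LZy24 than in CZy24. Of 16 mitosis genes 11 were higher, or 13 adjusted over the list alone (set adjusted p = 4.22e-06, adjusted p = 0.306 with an estimated correlation). CDC20.1, an activator of the anaphase-promoting complex, was at 607 ± 75.9 against 205 ± 21.3 (1.56 ± 0.19, adjusted p = 1.61e-05) and CDKB2;1 at 316 ± 28.3 against 95.9 ± 16.6 (1.72 ± 0.21). CYCB2;1 (6.4, 3.69 and 5.54) was listed at 0 in CZy24. Of 14 DNA replication genes 8 were lower (set adjusted p = 0.000491, adjusted p = 0.244 with an estimated correlation). They include MCM5 (7.25 ± 1.55 against 35.0 ± 2.82, -2.14 ± 0.41) and E2FB (19.3 ± 1.43 against 64.1 ± 13.9, -1.66 ± 0.21). RKD4 was at 80.0 ± 9.73 against 305 ± 43.6 (-1.91 ± 0.17, adjusted p = 8.53e-07) and MPK3 at 4.16 ± 0.60 against 23.5 ± 4.98 (-2.23 ± 0.26). The Polycomb gene CLF was at 13.2 ± 0.87 against 44.9 ± 2.61 (-1.69 ± 0.32) and the demethylase DML2 at 10.4 ± 2.68 against 1.54 ± 0.92 (2.20 ± 0.41). SSP (0.54, adjusted p = 0.406) was not called. Of 7 sperm and pollen markers 1 was higher and 1 lower (set adjusted p = 0.985), and no marker of synergids, the central cell or the seed coat was called. ER, at 1.63 ± 1.05 against 0.18 ± 0.05, was called (1.08 ± 0.36, adjusted p = 0.0314). It lost the call without LZy24 replicate 2 (1.13) or 3 (0.78), without CZy24 replicate 1 (1.085), 2 (1.11) or 3 (1.05), without LZy24 replicates 1 and 3 together (0.985) and after quantile normalization (0.215).

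Stress and wounding genes were lower in LZy24, 6 of 9 (set adjusted p = 0.0108, adjusted p = 0.635 with an estimated correlation). ZAT12 was at 15.3, 56.8 and 16.9 against 78.85, 334 and 364.5 (-3.06 ± 0.49, or -1.89 and not called without LZy24 replicates 1 and 3). The mRNA decay list (2 of 14 lower, 0.0402, adjusted p = 0.244 with an estimated correlation), the H4 list (none of 8 called, or 1 lower adjusted over the list alone, 0.0402, adjusted p = 0.684 with an estimated correlation) and the ribosomal protein list (12 higher and 7 lower of 313, 0.00038, adjusted p = 0.718 with an estimated correlation) passed too. The decapping enzyme DCP2 was at 53.4 ± 4.28 against 125 ± 22.0 (-1.195 ± 0.19). The helicase RH36 (26.1 ± 5.33 against 1.38 ± 0.69, 3.53 ± 0.37) was higher and NUC2 (38.1 ± 7.83 against 101 ± 14.3, -1.40 ± 0.19) lower in the ribosome biogenesis list (2 higher and 1 lower of 16, 0.531). The other higher gene, BRX1-1, was at 40.9, 0 and 54.7 in LZy24. It lost its call without replicate 3 (2.63) and turned to -0.07 without replicates 1 and 3. In total 2165 genes were higher and 2175 lower, the higher share of 49.9% being 57.5% after median of ratios scaling (2459 and 1820). With LZy24 replicate 2 alone, whose 10 genes near 0 match CZy24, 1683 genes were called, 1564 of them also called with all libraries.

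The difference between the crosses changed from 14 to 24 hours in 4095 genes, 2259 towards LZy and 1836 towards CZy (3064 without LZy14 replicate 3, 4242 without CZy14 replicate 3). DNA replication genes turned from higher to lower in LZy, 7 of 14 called, or 8 adjusted over the list alone (set adjusted p = 0.000188, adjusted p = 0.254 with an estimated correlation). MCM5 was at 24.7 ± 12.5 and 2.84 ± 0.90 in LZy14 and CZy14 and at 7.25 ± 1.55 and 35.0 ± 2.82 in LZy24 and CZy24 (change -4.78 ± 0.58, adjusted p = 4.95e-05). E2FB was at 39.3 ± 2.85 and 22.2 ± 3.32, then 19.3 ± 1.43 and 64.1 ± 13.9 (adjusted p = 4.44e-05). Of 2 synergid markers 1 moved towards CZy, or 2 adjusted over the list alone, as did 2 of 7 sperm and pollen markers, a set that did not pass (set adjusted p = 0.343). None of 6 central cell and endosperm markers was called, with a median of 0.78 towards LZy (0.343). Mitosis genes moved towards LZy, 6 of 16 called, or 9 adjusted over the list alone (set adjusted p = 0.000696, adjusted p = 0.734 with an estimated correlation). CDC20.1 went from 273 ± 13.6 and 354 ± 68.3 to 607 ± 75.9 and 205 ± 21.3. With LZy24 replicate 2 alone 1749 genes were called.

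**Figure D3:**
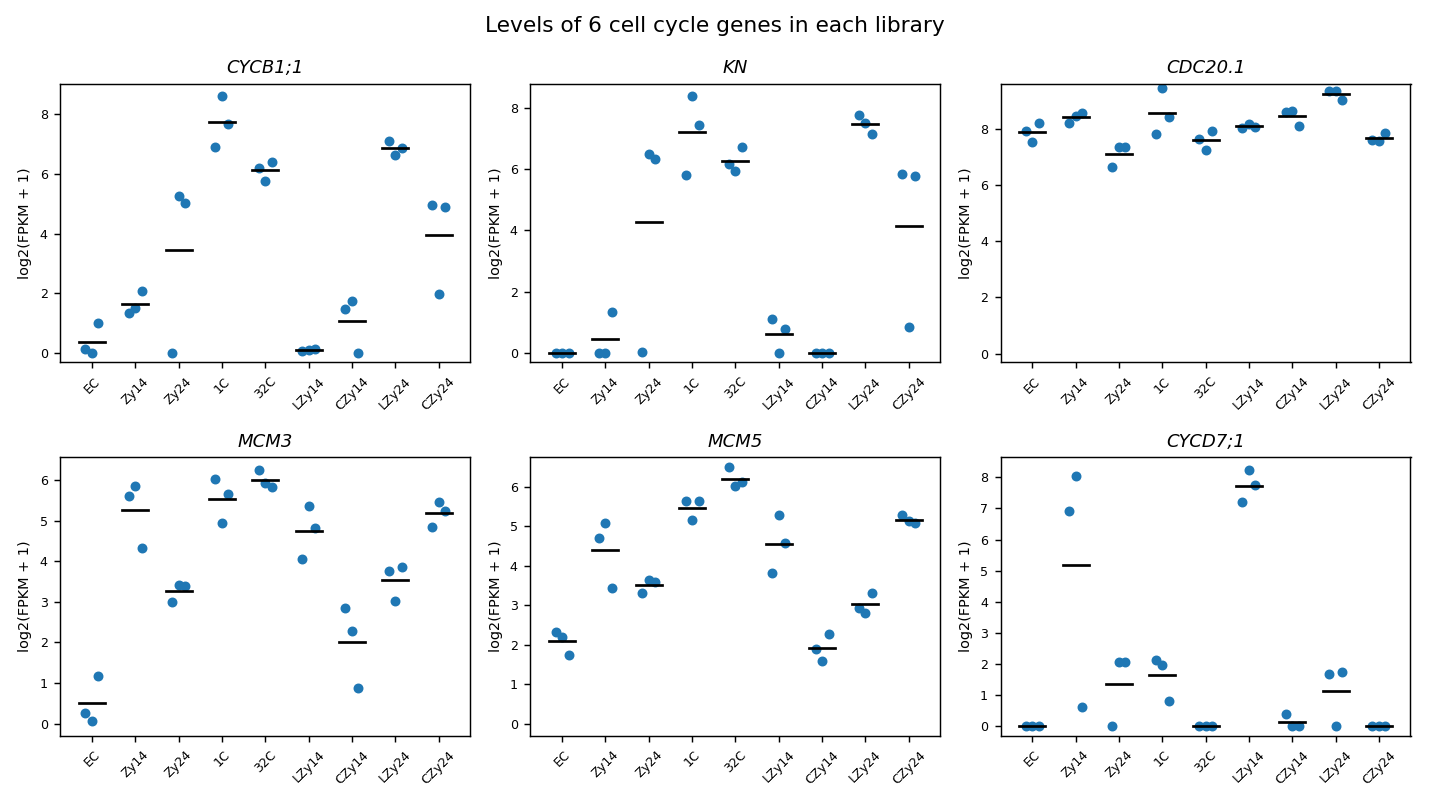
Levels of CYCB1;1, KN, CDC20.1, MCM3, MCM5 and CYCD7;1 as log2(FPKM + 1) on the vertical axis in the 9 groups on the horizontal axis, where each point is 1 library and each line the mean of 3. MCM3 and MCM5 are higher in LZy14 than in CZy14 and lower in LZy24 than in CZy24, and CDC20.1 is highest among zygotes in LZy24.

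Hybrids of both crosses were compared with Col zygotes at each hour. At 14 hours the RING/U-box gene AT3G14250 was at 529.7 ± 49.5 in LZy14 and 244 ± 119 in CZy14 and listed at 0 in Zy14 (adjusted p = 3.71e-13). At 24 hours it was at 669.8 ± 113 and 889.9 ± 25.1 against 0 (adjusted p = 3.86e-14). AT2G05400, of a ubiquitin-specific protease family, was listed at 0 in both Col groups and at 635 ± 108 and 71.7 ± 37.0 at 14 hours and 123.4 ± 18.1 and 192 ± 18.3 at 24 hours. CDC20.2 was higher in 14-hour hybrids (2.18 ± 0.29, adjusted p = 0.000208) at 100.5 ± 4.81 and 28.5 ± 3.92 against 11.3 ± 3.40. ICE1 was lower (-3.81 ± 0.40), at 0, 0 and 0.03 and 0.68, 0.14 and 6.22 against 22.4 ± 11.2. No list passed the set test at 14 hours, the lowest adjusted p being 0.266. There 1 of 2 synergid markers was higher, and 1 of 7 sperm and pollen and 1 of 6 central cell markers were lower. At 24 hours AGO9 was lower in hybrids, at 70.6 ± 5.75 and 177 ± 28.8 against 393 ± 29.1 (-1.81 ± 0.12, adjusted p = 3.75e-08). So were SSP (8.07 ± 1.23 and 5.70 ± 2.85 against 29.1 ± 5.19, -1.99 ± 0.38) and ER (1.63 ± 1.05 and 0.18 ± 0.05 against 8.08 ± 0.80, -2.40 ± 0.31). RKD3 (338 ± 23.1 and 264 ± 102 against 104 ± 15.7, 1.49 ± 0.25) and BSK1 (11.6 ± 2.00 and 9.46 ± 1.97 against 2.15 ± 0.25, 1.85 ± 0.28) were higher. AGO9 and SSP also fell, and RKD3 and BSK1 also rose, from Zy24 to 1C in Col. Whether hybrid and Col zygotes differed in stage at 24 hours was not tested. The ribosomal protein set was higher at 24 hours, with 16 genes higher and 2 lower of 313, or 17 and 3 adjusted over the list alone (set adjusted p = 8.65e-10, adjusted p = 0.683 with an estimated correlation). Of 7 photosynthetic genes 4 were higher (0.107), of 7 sperm and pollen markers 3 (0.526) and of 6 central cell markers 1, or none adjusted over the list alone (0.557). Of 2 synergid markers 1 was lower only when adjusted over the list alone.

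At 14 hours 307 genes were higher and 530 lower in hybrids (198 and 350 without LZy14 replicate 3, 407 and 682 without CZy14 replicate 3), the higher share of 36.7% being 49.6% after quantile normalization (419 and 425). The count fell to 306 with only the compared groups in the fit and to 539 at a filter of FPKM at least 5. At 24 hours 1760 genes were higher and 2034 lower, or 1838 and 1826 after median of ratios scaling and 1561 and 2409 after scaling to equal sums. Of the called genes 81 were higher at both hours against 29 for independent lists and 65 lower at both against 57.

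**Figure D4:**
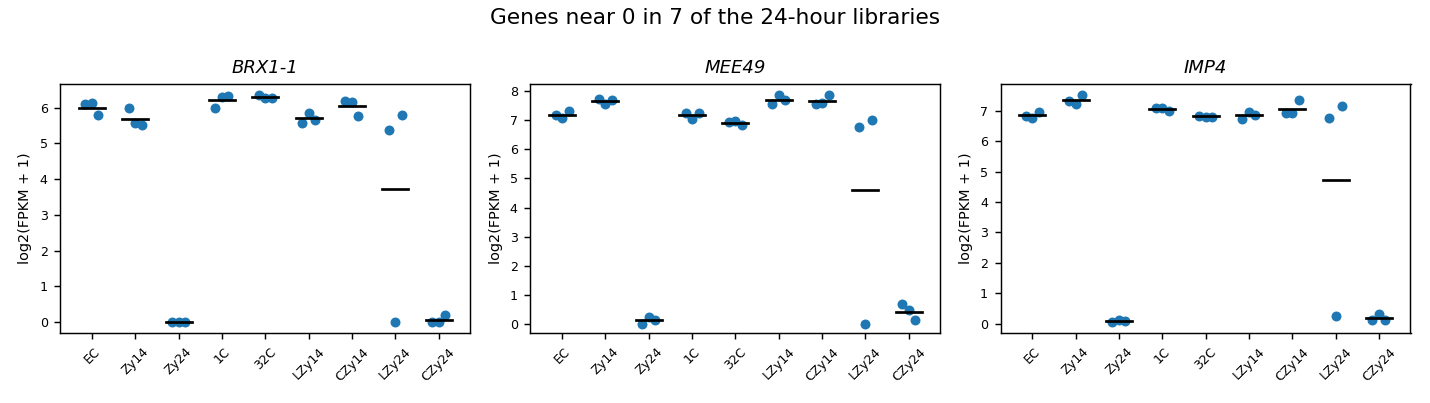
Levels of BRX1-1, MEE49 and IMP4 as log2(FPKM + 1) on the vertical axis in the 9 groups on the horizontal axis, where each point is 1 library and each line the mean of 3. The genes are near 0 in all Zy24 and CZy24 libraries and in LZy24 replicate 2, and present in LZy24 replicates 1 and 3 and the other 6 groups.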

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

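The tests weighed in this part, the counts of other splits of the libraries included, were written down after the results were seen, except the removal of the highest genes. The scalings were planned as alternatives, but their use as a test of the scale of the values was written down after the results were seen. The change of the difference between the crosses from 14 to 24 hours is given here because the reciprocal difference, tested as an interaction, differed between the hours in 4095 genes. Among the named genes, DNA replication factors moved towards CZy: MCM5 by -4.784 (SE 0.58, adjusted p = 4.95e-05), MCM3 by -4.387 (adjusted p = 0.000348) and E2FB by -2.465 (adjusted p = 4.44e-05). The means of MCM5 were 24.7, 2.84, 7.25 and 35.0 FPKM in LZy14, CZy14, LZy24 and CZy24. Mitotic genes moved towards LZy: CYCB2;1 by 2.609 (adjusted p = 0.00013), CDC20.1 by 1.915 (adjusted p = 0.000136) and CDKB1;2 by 1.447 (adjusted p = 0.0062). The cyclin CYCD7;1 changed by -6.446 (adjusted p = 0.0129), a call lost at a pseudocount of 0.1 (-7.29).

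Outside the cell cycle, the largest changes among the named genes were AGL102 (9.48, adjusted p = 3.48e-06), AT1G11220 (7.817, adjusted p = 2.98e-05) and AT1G69660 (6.821, adjusted p = 8.23e-05) towards LZy. Towards CZy they were YSL3 (-6.326, adjusted p = 5.11e-05) and AGL67 (-6.006, adjusted p = 5.61e-05). AGL102 was listed at 0 in LZy14 and CZy24 and at 14.2, 14.9 and 9.47 in CZy14 and 109, 15.2 and 79.1 in LZy24. Fitted changes of genes listed at 0 in a group depend on the value added before the logarithm, and LZy14 replicate 3 lies near a mixture of the other LZy14 libraries, without which 3064 genes were called.

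Of 100 splits of the libraries drawn at random, only the real one reached 4095 genes, the highest other giving 2371. These splits mixed the crosses within each hour, so they also removed the plain difference between the crosses. They therefore cannot decide whether chance explains the change of the reciprocal difference. For the hybrids against Col, counted with both crosses as 1 group, 5 of the 84 splits at 14 hours gave at least the real count of 354 (highest other 1767), so chance cannot be excluded there. At 24 hours 2 of 84 splits reached the real 2634 (highest other 3169), a share under 0.05. The higher counts of other splits point to a structure of the samples. At 14 hours they set LZy14 apart (1767) or CZy14 apart (680) or mixed CZy14 with Zy14 (593 and 473), and at 24 hours the 1 higher split set CZy24 apart (3169). Setting LZy24 apart gave 2482 and no mixed split more than 253, so the count at 24 hours is not specific to hybrids against Col. The 8 comparisons of 3 with 3 libraries have 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, reached its count. The counts were 4750 (highest other 129) for Zy14 against EC, 6971 (25) for Zy24 against Zy14, 5834 (0) for 1C against Zy24, 3887 (0) for 32C against 1C. They were 6797 (2) and 8237 (36) for the LZy and CZy steps, 2187 (79) for LZy14 against CZy14 and 4340 (38) for LZy24 against CZy24.

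The 10 genes near 0 (at most 0.61 FPKM) in Zy24, CZy24 and LZy24 replicate 2, and present in LZy24 replicates 1 and 3 and in 18 libraries of other hours and stages (except AT1G50000 at 0.07 in CZy14 replicate 3), were found by a search chosen after the data were seen. In LZy24 replicates 1 and 3 the median over the genes was 111.8% of LZy14. The search required the genes to be present in these libraries, so a gene lost there could not enter the list. The value therefore cannot decide whether transcripts were lost between 14 and 24 hours in LZy24. Removal of ribosomal RNA sequences from 7 libraries before the values were made stays open as an explanation. The products of 6 of the 10 genes name ribosomal RNA, against 24 of 10469 others as high (Fisher's exact two-sided p = 6.74e-14). These 6 products are described as proteins that process or methylate ribosomal RNA, not as ribosomal RNA. The count therefore does not show that removing ribosomal RNA sequences would take out their transcripts. The 18S locus AT3G41768 is at 25.25 or less in the 7 libraries and at 791 and 621 in LZy24 replicates 1 and 3. Across the 18 libraries of other hours and stages it ranged from 60.45 to 1829.36. For Zy24 and CZy24, where the highest of the genes stands at 0.98% of its 14-hour mean, loss and removal cannot be told apart, because all 6 libraries have the low 18S locus.

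Mitotic transcripts were higher in LZy24 than in CZy24, with a median log2 difference of 2.60 over 16 genes. A difference in processing among the LZy24 libraries stays open, since it can be checked only in LZy24 replicate 2, where the median was 2.44, and 1 library excludes nothing. LZy24 zygotes further along than CZy24 zygotes may explain the pattern, as the difference correlated with the step from Zy24 to 1C across 17563 genes at r = 0.178 with LZy24 replicate 2 alone, between the bounds of 0.1 and 0.3 set for deciding. With all 3 LZy24 libraries 1229 called genes went the same way against 655 for independent lists and 529 the opposite way against 654. The DNA replication list went against the step to 1C, with 8 of 14 genes lower in LZy24 while 6 rose and 1 fell from Zy24 to 1C. From 14 to 24 hours, however, 1 rose and 4 fell in Col, 0 rose and 3 fell in the LZy zygotes, and 8 rose in the CZy zygotes. Earlier, from EC to Zy14, 10 rose and 1 fell. In that direction, 5 were higher and 2 lower in LZy14 than in CZy14. This list therefore does not decide the question. The parental genotypes themselves stay open and were not tested.

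More genes were higher than lower in Zy14 against EC, at 76.0% of the calls. Synergid transcripts in EC replicate 3 and Zy14 replicate 1 were seen as DD31 at 57.9 and 214 and LURE1.2 at 65.8 and 300.3. A share of 76.1% without these libraries argues against their synergid transcripts as the cause. EC replicate 1 held both transcripts at lower levels and stayed in that fit, so the share speaks only for the libraries left out. A few egg cell genes taking a large share of the values are argued against as the whole cause by a share of 73.2% with the 39 genes among the 10 highest of a library removed and the rest scaled to equal sums, against 80.9% with equal sums alone. The scale of the deposited values stays open, with 66.9% after median of ratios scaling and 49.0% after quantile normalization, which forces equal distributions. A rise of transcription in the zygote could give the same pattern and was not tested.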

How the results depend on the processing

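The fits without EC replicate 3 and Zy14 replicate 1 and without LZy24 replicates 1 and 3 were chosen after the data were seen. Over 577 results for named genes and 8735 values under the alternatives, 8168 kept their direction and side of the threshold, 556 lost the call, 9 gained one and 2 reversed. These were EC1.3 in Zy14 against EC after quantile normalization (0.28) and BRX1-1 in LZy24 against CZy24 without LZy24 replicates 1 and 3 (-0.067), where the libraries that list it are left out. The cause of the first was not tested. Quantile normalization ended 39 calls, a pseudocount of 0.1 36, the compared groups alone 31, no filter 18, median of ratios scaling 14, equal sums 11, the replicate number as a block 7, and leaving out 1 library 337 of 3876. Leaving out LZy24 replicates 1 and 3 ended 59 of 202, and leaving out EC replicate 3 and Zy14 replicate 1 ended 4 of 120.

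Counts of called genes stayed within 1.5 times the reported count under the scalings, pseudocount, filters and block for all 11 comparisons, except hybrids against Col at 14 hours, with 539 genes at a filter of FPKM at least 5 and 306 with only the compared groups. Fewer genes and fewer libraries enter these fits. Without LZy24 replicates 1 and 3, which leaves 1 LZy24 library assumed to vary like the other groups, 4119 genes were called in LZy24 against LZy14 (3860 of them also with all libraries), 1683 in LZy24 against CZy24 and 1749 in the change of the reciprocal difference. With the replicate number as a block the genes shared by the 3 steps from 14 to 24 hours were 2409, against 2395.

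Leaving out 1 library gave 3778 to 5042 genes for Zy14 against EC, 6174 to 6970 for Zy24 against Zy14, 5121 to 5973 for 1C against Zy24, and 2790 to 3606 for 32C against 1C. It gave 5742 to 6642 and 7548 to 7845 for the LZy and CZy steps, 1267 to 2184 for LZy14 against CZy14, 3272 to 4219 for LZy24 against CZy24, 3064 to 4242 for the change of the reciprocal difference, and 548 to 1089 and 2736 to 3857 for hybrids at 14 and 24 hours. Genes switched on were 383 to 587, 65 to 114, 344 to 432 and 361 to 426 in the 4 Col steps, and switched off 13 to 28, 518 to 724, 143 to 215 and 85 to 102. Differences in genes detected were 2068 to 2550, -2591 to -2095, 762 to 1150, 481 to 663, -890 to -472 (LZy14 and CZy14) and 875 to 1163 (LZy24 and CZy24).

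With FPKM of at least 10 required, genes switched on numbered 223, 16, 150 and 211 and switched off 2, 267, 46 and 23. With under 0.5 required, 7 were off in Zy14, 32 on in Zy24 and 44 off in 32C. Genes detected at FPKM of at least 0.1 differed by 2833 (Zy14 and EC), -3242 (Zy24 and Zy14) and 1518 (32C and 1C), and at 5 by 1582, -825 and 279 in the first 3 steps, while LZy24 then held fewer genes than CZy24 (-64). The thresholds themselves set these counts, and the cause of the reversal was not tested. Of 213 list tests 43 passed at the preset correlation and 2 with an estimated correlation. By the estimated depth FPKM of 0.1 is 1.14 to 2.33 fragments per kb, so the counts at 0.1 rest on few fragments. How far depth limits these counts was not tested.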

Other observations

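The genes in the first 2 paragraphs were chosen after their values were seen. Levels of AGO5, AGO9, RKD2 and RKD4 over the Col series are given here, and no difference between their courses was tested. AGO5 was at 556 ± 97.7 FPKM in EC, 290.5 ± 53.1 in Zy14, 18.5 ± 2.89 in Zy24, 191 ± 29.8 in 1C and 66.8 ± 6.79 in 32C. AGO9 was at 1707 ± 259 in EC and 93.7 ± 5.21 in 1C. RKD2 was at 1695, 1802 and 1520 in EC and at 14.3, 0 and 6.64 in Zy24, while RKD4 was highest in the zygotes at 14 hours. CYP78A5, a cytochrome P450, was listed at 0 in EC and stood at 1001 ± 111 in Zy24, 1521 ± 87.7 in LZy24 and 814 ± 48.9 in CZy24.

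SADHU3-2, without a described product, was listed at 0 in all 15 Col libraries and in CZy14, and was at 26.5, 45.7 and 30.1 in LZy14, 35.3, 24.35 and 27.4 in LZy24 and 49.0, 42.7 and 40.6 in CZy24. The median Spearman correlation between libraries of a group ran from 0.910 in Zy14 to 0.981 in 32C.

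The test in this paragraph was chosen after the result was seen. Differences between the crosses that persist from 14 to 24 hours were a hypothesis for the 2187 and 4340 genes called at the separate hours. The test argues against it as a general account: 260 genes were called in the same direction at both hours, where independent lists would share 252, and 256 in opposite directions against 252.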
